A study of Pan troglodytes with 6 samples.

How the data were processed

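RNA from the cerebellum and the liver of chimpanzees (Pan troglodytes) was profiled on Affymetrix Human Exon 1.0 ST arrays, which carry probes designed on the human genome and spread along the exons of each gene. There were 3 cerebellum arrays and 3 liver arrays, each labelled as a biological replicate. By the labels, replicate 1 was a female of 27 years, replicate 2 a male of 37 years and replicate 3 a male of 30 years, in both tissues. Per the labels' protocols, total RNA was extracted with TRIzol, ribosomal RNA was reduced with the RiboMinus kit, and sense-strand DNA was labelled with biotin. The submitters' processing notes name GCOS, the scanner software of the array's maker, without a version.

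The deposited values are intensities on a linear scale, 1 per array for each of 15143 features (transcript clusters, the array's units of about 1 gene). The method of background correction, the summary of probes into features and any choice of probes that match both species are not given in the sources used here. The values themselves show that some background had been subtracted, since 93 values on each array lay below 0 and the lowest was -169.95. The 6 arrays hold the same 15143 values in different orders, with 0 sorted positions at which they differ, so the authors' deposited intensities had been quantile normalized. The median intensity was 96.3 and the highest 6527 on each array. Such a table cannot show a difference in total signal between arrays or tissues. Precision is limited by the number of arrays, and probe mismatches between human and chimpanzee sequence can change the level of one gene against another.

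Gene names came from the platform annotation, in which 12685 features had 1 gene symbol, 1780 had several and 678 had none. No gene was named from a feature with several symbols. Where features shared a symbol, the one with the highest mean log2 level over the 6 arrays was kept, which left 12584 genes and set aside 101 dimmer features. The symbols are those of the annotation, and features of near-identical gene copies, such as members of the CYP3A and alcohol dehydrogenase families, can share signal.

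Values were transformed as log2(intensity + 16.8), where the pseudocount is the 10th percentile of all values, and values below 0 were first set to 0. That floor of 0 was chosen after the values were seen, while the pseudocount rule, the test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Differences on this scale understate the change of dim genes. Each feature was compared between the tissues with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with no block and no filter. P values were adjusted by Benjamini-Hochberg over all 15143 features, with a threshold of 0.05 and, as a second criterion, a difference of at least 2-fold. All differences are cerebellum minus liver. The p values cover the spread between 3 animals per tissue. A permutation of 3 against 3 arrays cannot give a two-sided p under 0.1, so no permutation p is given for single genes.

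The 31 gene lists covered neuronal and glial cell types of the cerebellum, hepatocyte functions, other cell types that either tissue could hold, and general cell functions. They held 669 genes, of which 434 were measured. A further 73 features with several symbols named a listed gene and were not used. Members past the threshold were counted after adjustment over all features and adjusted over the list alone. The shift of each list against all other genes was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated from the residuals. The named genes were the 5 with the largest difference in each direction among called genes whose tissues did not overlap, the 2 largest of each cerebellum or liver list with up to 2 called in the opposite direction, and the largest in each direction of the other lists. Genes named outside this rule were chosen after their values were seen and are stated as such. The rule gave 64 genes, including 2 Y-linked genes used to check the sex labels. The plan also named XIST for this check, but XIST was not analysed here.

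The test was tried on simulated data with the 15143 features and their measured levels and spread, in which 200 features were changed. It recovered 31 of 100 features changed by 1 on the log2 scale and 86 of 100 changed by 2, and 3 of its 120 calls (2.5%) were false. In the real data 50.6% of features were called, a far larger share than was changed here. The recovered shares therefore do not give the sensitivity of the real comparison. A shifted list was found and 0 of 19 unshifted lists were called. The simulated genes varied independently, while estimated correlations of the real lists reached 0.55. The trial therefore does not test false list calls where genes vary together.

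Alternatives were a block on the replicate number, renewed quantile normalization, centring on the median, pseudocounts at the 1st and 25th percentiles (2.19 and 38.3), removal of features under the 25th percentile of mean level, a trended and robust variance prior, a test against a 2-fold difference (treat), the mean of all features of a gene, an estimated correlation in camera, and each array left out in turn. Added after seeing the data were an alignment of the arrays on ribosomal protein, proteasome and oxidative phosphorylation genes, removal of features with a value below 0 on any array, and a fit without cerebellum replicate 1 and liver replicate 3. Shifts of a list on 1 array were set against 10000 random lists matched on intensity. Plots were drawn with matplotlib 3.10.9.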

Results

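The series profiled 3 cerebellum and 3 liver samples of chimpanzees on an exon array designed for human genes. Its title states the wider purpose of profiling expression in closely related species, and the comparison possible with these samples is that of the 2 tissues. Each array gave an intensity for 15143 features, with the same distribution on all 6 arrays. Across features, arrays of the same tissue correlated with Pearson's r of 0.947 to 0.977 in cerebellum and 0.906 to 0.950 in liver, against 0.445 to 0.507 between tissues. Features are not independent replicates, so these values describe the arrays. The first principal component, which parted the tissues, took 87.3% of the variance. The second took 5.78% and set liver replicate 1 against liver replicate 3. The Y-linked genes EIF1AY and UTY went with the sex labels. On the 2 arrays labelled female EIF1AY was 8.48 in cerebellum and -4.02 in liver and UTY was 11.7 and 8.49, whereas the lowest value of either gene on the 4 arrays labelled male was 115.

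The genes with the largest differences are known from neurons and glia on one side and from the liver on the other. On the log2 scale with its pseudocount of 16.8, the largest difference toward cerebellum was that of SNAP25, a protein of synaptic vesicle fusion, at 4190 ± 512 in cerebellum and 24.1 ± 7.09 in liver (intensity, mean ± SD, n = 3 per tissue here and below). Its log2 difference was 6.70 with a standard error of 0.20 (limma, adjusted p = 1.51e-07). STMN2, a regulator of microtubules in neurons, GPM6B, a membrane protein of neurons and glia, SNCB, which encodes beta-synuclein, and SCN2A, a neuronal sodium channel, followed with log2 differences of 6.60, 6.18, 6.10 and 6.09. The mean of SNCB in liver lay below 0, at -0.996. The largest difference toward liver on this scale was that of CYP3A4, a drug-metabolising cytochrome P450, at 7.95 ± 5.12 in cerebellum and 3684 ± 195 in liver, with a log2 difference of -7.25 and a standard error of 0.20. The fibrinogen chains FGB and FGA, the lipoprotein component APOB and the protease inhibitor SERPINA3 had log2 differences of -7.23, -7.01, -7.04 and -7.03. These differences and their order depend on the pseudocount, since the mean in the dimmer tissue was under 16.8 for all but SNAP25 and SERPINA3, and that of SERPINA3 rests on 1 cerebellum value of 47.5 beside 13.2 and 4.20. At a pseudocount of 2.19 SNCB and STMN2 exceeded SNAP25, with log2 differences of 9.02, 7.68 and 7.35, and at 38.3 FGB exceeded CYP3A4, with -6.48 and -6.34. In all, 4045 features were higher in cerebellum and 3617 were higher in liver (limma, adjusted p under 0.05), together 50.6% of those tested. With a difference of at least 2-fold, 2600 and 2397 features passed. The 3 values of one tissue lay entirely above those of the other for 4686 and 4305 features, 59.4% of all, where chance gives 10%. Among the 12584 named genes, 3327 and 3074 passed.

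These counts depend on how the tissues are scaled against each other. With the arrays aligned on ribosomal protein, proteasome and oxidative phosphorylation genes, 69.1% of called features were higher in cerebellum, against 52.8% with the deposited scale, because that alignment moves the median log2 difference of all features from 0.04 to 0.38. It moves every difference toward cerebellum, so the loss of a call toward liver under this alignment is partly built in. A test against a 2-fold difference (treat) in place of a limit on the estimate left 1295 features higher and 1350 lower.

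**Figure D1:**
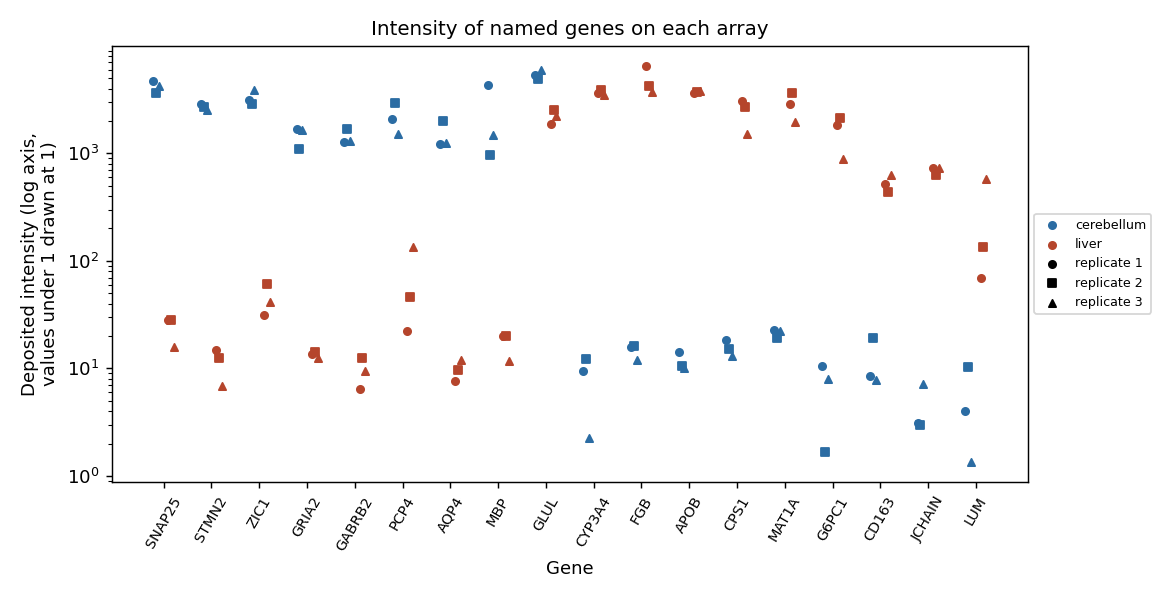
Deposited intensity (log axis, values under 1 drawn at 1) of 18 named genes on each of the 6 arrays, with cerebellum in blue, liver in red and a symbol for each replicate. SNAP25 lies near 4190 in cerebellum and 24.1 in liver, CYP3A4 near 7.95 and 3684, while GLUL is high in both tissues and MBP and LUM differ widely between animals of one tissue.

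Genes of synaptic transmission were higher in cerebellum almost without exception. Of 19 measured genes of synaptic vesicles and transmitter release, 18 were higher and 0 lower, also adjusted over the list alone, with a median log2 difference of 3.71. The remaining gene, the vesicular GABA transporter SLC32A1, which is named outside the rule, had a difference of 0.51 (limma, adjusted p = 0.134). SV2B, a synaptic vesicle glycoprotein, was at 1431 ± 127 in cerebellum and 13.9 ± 4.64 in liver. Of 19 genes of glutamate receptors and the postsynaptic scaffold, 17 were higher and 1 was lower, the same numbers adjusted over the list alone. The AMPA receptor subunit GRIA2 was at 1483 ± 337 against 13.4 ± 0.810, and the kainate receptor subunit GRIK2 differed by 5.04 on the log2 scale. The gene that went the other way was the metabotropic receptor GRM7, at 74.5 ± 14.3 in cerebellum and 155 ± 33.6 in liver (log2 difference -0.91, limma adjusted p = 0.00734). That call was lost when arrays were aligned on the general genes (log2 difference -0.57, limma adjusted p = 0.0849). Of 11 genes of GABA and glycine receptors and GABA synthesis, 9 were higher and 0 lower, also adjusted over the list alone. GABRB2 and GABRG1, subunits of the GABA-A receptor, differed by 5.78 and 4.20. Of 13 voltage-gated ion channels, 12 were higher, or 13 adjusted over the list alone, and the potassium channel KCND2 reached 946 ± 103 against 12.5 ± 2.74.

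Markers of the cell types of the cerebellum were also mostly higher there. All 11 measured granule cell markers were higher, adjusted over all features or adjusted over the list alone, with a median of 4.07. ZIC1, a transcription factor of granule cells, was at 3295 ± 530 in cerebellum and 44.4 ± 14.9 in liver, and the protocadherin FAT2 differed by 5.69. Of 13 Purkinje cell markers, 12 were higher in either adjustment, with a median of 2.88. PCP4 was at 2176 ± 709 against 67.7 ± 59.8, and CALB1, which encodes calbindin, differed by 4.45. Of 14 markers of Bergmann glia and astrocytes, 10 were higher and 2 lower, or 11 and 2 adjusted over the list alone. The water channel AQP4 and the glutamate transporter SLC1A3 differed by 5.79 and 5.55. The 2 lower markers were ALDH1L1, a folate enzyme that liver also expresses, at 82.7 ± 2.48 in cerebellum and 630 ± 371 in liver, and TNC, a matrix protein, at 9.76 ± 1.67 and 68.6 ± 73.9. The call of TNC (limma, adjusted p = 0.0468) was lost when any 1 of the 3 cerebellum arrays was left out (adjusted p from 0.0955 to 0.117), at a pseudocount of 38.3 (adjusted p = 0.0843) and with arrays aligned on the general genes (adjusted p = 0.0783). Its liver values were 28.8, 23.1 and 154, and without liver replicate 3 the log2 difference was -0.69 in place of -1.35 (adjusted p = 0.0128). Of 13 oligodendrocyte and myelin markers, 8 were higher and 1 lower in either adjustment, with a median of 1.32. MBP, a main myelin protein, was at 2248 ± 1793 in cerebellum and 17.2 ± 4.85 in liver, and its 3 cerebellum values were 4297, 966 and 1481. UGT8, an enzyme of myelin lipid synthesis, differed by 3.03. OPALIN, a myelin protein, was the lower one at 156 ± 14.8 against 250 ± 53.7 (log2 difference -0.61, limma adjusted p = 0.0309), and its call was lost without cerebellum replicate 1, 2 or 3 or liver replicate 2 or 3, with adjusted p from 0.0531 to 0.108, and with arrays aligned on the general genes (log2 difference -0.27, adjusted p = 0.442).

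The 8 cerebellum lists held 97 calls toward cerebellum and 4 toward liver among 113 memberships. All 8 shifted upward against other genes (camera, adjusted p from 2.32e-11 to 0.00347). With an estimated correlation the calls of the synaptic vesicle and glutamate lists held (adjusted p = 0.0332 for both). The other lists did not pass, with adjusted p = 0.0555 for ion channels, 0.0760 for granule cells, 0.0877 for GABA genes, 0.146 for Purkinje cells, 0.197 for astrocytes and 0.221 for oligodendrocytes. Such a loss does not by itself show that genes of a list vary together. For the glutamate list camera's adjusted p rose from 1.71e-07 although its estimated correlation was -0.010. Cerebellum replicates 1 and 2 lay on opposite sides in all 8 lists. Each shift is taken against the other 2 arrays, so the 3 shifts of a gene balance and opposite signs are partly built in. Against the mean of the other 2 cerebellum arrays (median over the list, log2), oligodendrocyte markers lay at 0.81 in replicate 1 and -0.26 in replicate 2, Purkinje markers at -0.41 and 0.60, astrocyte markers at -0.32 and 0.31, GABA genes at -0.23 and 0.31, granule cell markers at -0.27 and 0.18, glutamate genes at -0.17 and 0.25, synaptic vesicle genes at -0.17 and 0.12, and ion channels at 0.05 and -0.16. The pair of replicates 1 and 3 was the closest (r = 0.977) and that of replicates 1 and 2 the least close (r = 0.947).

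Genes of proteins that the liver secretes into plasma were higher in liver. All 17 measured plasma proteins, all 20 genes of coagulation and fibrinolysis and all 15 complement components were higher in liver, also adjusted over the list alone, with median log2 differences of -6.24, -5.04 and -5.13. RBP4, the retinol carrier, was at 18.8 ± 6.78 in cerebellum and 4507 ± 538 in liver. C4BPA, a regulator of complement, and C1S, a complement protease, differed by -6.25 and -6.23. All 10 apolipoprotein and lipoprotein genes were higher in liver, with a median of -4.34, and APOH differed by -6.97. All 10 cytochrome P450 genes of the xenobiotic list and all 10 phase II conjugation genes were higher in liver, with medians of -4.25 and -4.19, again also adjusted over the list alone. CYP3A5 differed by -5.84, though near-identical copies such as CYP3A4 can share its signal. NNMT and GLYAT, a methyltransferase and an acyltransferase, differed by -5.84 and -5.61.

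Metabolic functions of hepatocytes followed the same direction. Of 16 genes of bile acid synthesis and hepatobiliary transport, 15 were higher in liver, or 16 adjusted over the list alone, with a median of -4.09. SLC27A5 and CYP8B1, enzymes of bile acid conjugation and synthesis, differed by -4.76 and -4.71. The remaining gene, CYP7A1, the rate-limiting enzyme of the pathway and named outside the rule, had a difference of -1.68 (limma, adjusted p = 0.0768). All 22 genes of amino acid catabolism and all 12 of gluconeogenesis and glucose handling were higher in liver in either adjustment, with medians of -3.67 and -3.76. TDO2, which opens tryptophan breakdown, was at 2.84 ± 1.39 against 1509 ± 665, and MAT1A, which makes S-adenosylmethionine, differed by -6.17. The glucose transporter SLC2A2 and the glucose-6-phosphatase G6PC1 differed by -6.58 and -6.05. Of 9 genes of the urea cycle and ammonia handling, 6 were higher in liver and 1 in cerebellum, or 6 and 2 adjusted over the list alone, with a median of -3.50. CPS1, its first enzyme, was at 15.5 ± 2.64 against 2432 ± 824, and ARG1 differed by -5.37. The exception was GLUL, glutamine synthetase, which astrocytes also express, at 5404 ± 511 in cerebellum and 2208 ± 346 in liver (log2 difference 1.29, limma adjusted p = 4.93e-04). Of 12 hepatic transcription factors, 11 were higher in liver in either adjustment, with a median of -2.48, and NR5A2 and CEBPA differed by -4.18 and -3.21.

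The 11 liver lists held 148 calls toward liver and 1 toward cerebellum among 153 memberships, and all 11 shifted toward liver (camera, adjusted p from 1.23e-16 to 0.00304). With an estimated correlation the calls of the plasma protein and apolipoprotein lists held (adjusted p = 0.0332 for both). The others gave adjusted p = 0.0562 for complement, 0.0724 for coagulation, 0.0760 for gluconeogenesis and for transcription factors, 0.0810 for cytochromes P450, 0.124 for bile acids, 0.135 for phase II genes and amino acid catabolism, and 0.197 for the urea cycle. Liver replicate 3 stood apart in several of them. Against the other 2 livers its median shift was -0.91 for phase II genes, -0.84 for amino acid catabolism, -0.66 for the urea cycle, -0.52 for bile acids and -0.49 for gluconeogenesis, but -0.09 for plasma proteins and -0.04 for apolipoproteins. Liver replicate 1, which is part of the mean that replicate 3 is set against, lay at 0.40, 0.63, 0.60, 0.35, 0.43, -0.12 and -0.02 in the same order.

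**Figure D2:**
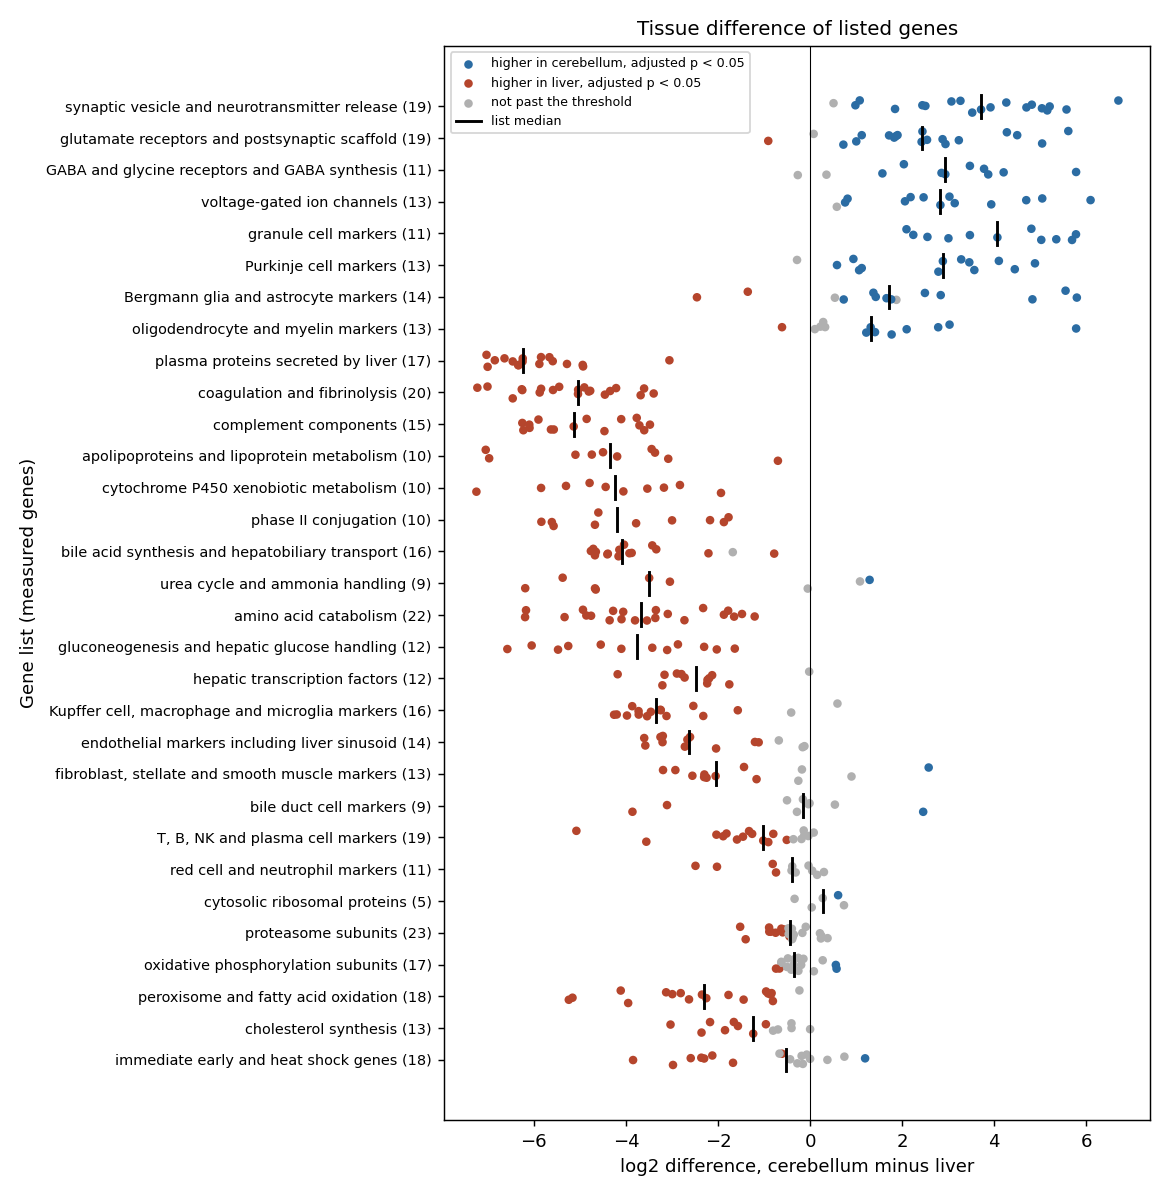
Log2 difference (cerebellum minus liver) of each measured member of the 31 gene lists, 1 point per gene, with a black bar at the list median and the number of measured genes in brackets. Blue and red points passed adjusted p under 0.05 in limma. Medians run from 4.07 for granule cell markers to -6.24 for plasma proteins.

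Markers of other cell types were mostly higher in liver. Of 16 markers of Kupffer cells, macrophages and microglia, 14 were higher in liver, or 15 adjusted over the list alone, with a median of -3.35. CD163, a macrophage scavenger receptor, was at 11.9 ± 6.35 against 528 ± 101. Markers of Kupffer cells, the macrophages of the liver, are on this list, so its direction is partly built in. Of 14 endothelial markers, 11 were higher in liver in either adjustment, with a median of -2.64, and FCN3 differed by -3.60. This list includes markers of the liver sinusoid, and FCN3 is also on the complement list, so its direction is partly built in. Of 13 markers of fibroblasts, stellate cells and smooth muscle, 9 were higher in liver and 1 in cerebellum in either adjustment. LUM, a matrix proteoglycan, was at 5.21 ± 4.55 against 262 ± 279, with liver values of 69.2, 135 and 582, and THY1, which neurons also express, was at 365 ± 109 against 53.1 ± 43.4. Of 19 markers of lymphocytes and plasma cells, 13 were higher in liver in either adjustment, with a median of -1.02. JCHAIN, the joining chain of immunoglobulins, was at 4.40 ± 2.36 against 696 ± 62.5. Without dim features the count of this list was 6. That filter also takes dim members off the lists, so a lower count need not be a lost call. Among 9 bile duct markers, ANXA4 and EPCAM, the second named outside the rule, were higher in liver by log2 differences of -3.86 and -3.11, and SPP1, a secreted phosphoprotein, was higher in cerebellum at 782 ± 795 against 98.9 ± 51.5, and the same numbers passed adjusted over the list alone. The cerebellum values of SPP1 were 1699, 338 and 307, and its log2 difference of 2.46 was 1.68 without cerebellum replicate 1 (limma, adjusted p = 0.0150). Among 11 markers of red cells and neutrophils, 4 were higher in liver, or 3 adjusted over the list alone, and 2 without dim features or with arrays aligned on the general genes. They were HBB, a globin chain, at -2.49, and S100A8, S100A9 and CSF3R, named outside the rule, at -2.02, -0.81 and -0.74. The macrophage, endothelial, lymphocyte and fibroblast lists shifted toward liver (camera, adjusted p = 1.71e-07, 5.98e-06, 1.62e-04 and 0.00848), and with an estimated correlation these did not pass (adjusted p = 0.197, 0.0810, 0.265 and 0.205). The bile duct and red cell lists did not pass (camera, adjusted p = 0.327 and 0.111). In liver replicate 3, macrophage markers lay 0.74, fibroblast markers 0.81, bile duct markers 0.55 and lymphocyte markers 0.60 above the other 2 livers, endothelial markers lay at 0.07 and red cell and neutrophil markers at -0.32. The red cell and neutrophil list mixes cell types, and 3 of its 11 genes lay above the other livers, among them HBB at 1.32.

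Among lists of general functions, those of lipid metabolism were mostly higher in liver. Of 18 genes of peroxisomes and fatty acid oxidation, 17 were higher in liver in either adjustment, with a median of -2.30 (camera, adjusted p = 1.53e-07, but adjusted p = 0.174 with an estimated correlation), and catalase, CAT, was at 36.7 ± 9.19 against 1989 ± 165. Of 13 genes of cholesterol synthesis, 8 were higher in liver in either adjustment, with a median of -1.24 (camera, adjusted p = 0.00214, but adjusted p = 0.224 with an estimated correlation), and MSMO1 differed by -3.03. In liver replicate 3 these 2 lists moved apart, by -0.58 and 0.77. Of 18 immediate early and heat shock genes, 8 were higher in liver and 1 in cerebellum in either adjustment. HMOX1, heme oxygenase, differed by -3.85, and the chaperone HSP90AA1 was the one higher in cerebellum, by 1.19. The shift of this list (camera, adjusted p = 0.0201) did not pass with an estimated correlation (adjusted p = 0.197). It was also lost without liver replicate 3 (adjusted p = 0.0598), in which the list lay 0.59 above the other 2 livers. Of 23 proteasome subunits, 10 were higher in liver, or 6 adjusted over the list alone, with a median of -0.45 (camera, adjusted p = 0.0114, but adjusted p = 0.467 with an estimated correlation) and PSMB2 at -1.52. This list lay at -0.39 in cerebellum replicate 1 and 0.35 in cerebellum replicate 2, and the oxidative phosphorylation list at -0.30 and 0.39. Without cerebellum replicate 1, cerebellum replicate 3 or liver replicate 2 the count was 5, and without liver replicate 3 it was 6. The shift of this list was lost when cerebellum replicate 1 and liver replicate 3 were both left out (adjusted p = 0.0862) and when arrays were aligned on general genes that include it (adjusted p = 0.0580). Of 17 oxidative phosphorylation subunits, 2 were higher in cerebellum and 2 in liver, or 0 and 0 adjusted over the list alone. They were NDUFA10 at 0.57 and COX4I1 at -0.74, with ATP5F1A at 0.56 and SDHA at -0.67 named outside the rule. The call of NDUFA10 was lost without cerebellum replicate 1 or 3 (adjusted p = 0.0655 and 0.0652), and that of COX4I1 without cerebellum replicate 1 or 3 or liver replicate 1 or 2 (adjusted p from 0.0579 to 0.0881). The call of COX4I1 was also lost with arrays aligned on general genes that include it (log2 difference -0.40, limma adjusted p = 0.225). Only 5 of 39 listed ribosomal protein genes were measured, and RPS6 was higher in cerebellum at 4539 ± 319 against 3035 ± 756 (limma, adjusted p = 0.0472). Adjusted over the list alone, 0 of the 5 passed, and the call of RPS6 was lost when any 1 array other than liver replicate 3 was left out (adjusted p from 0.0662 to 0.137). Its log2 difference of 0.61 was 0.39 without liver replicate 1 and 0.55 to 0.69 in the others of these fits. The shifts of the oxidative phosphorylation and ribosomal lists, with medians of -0.34 and 0.27, did not pass (camera, adjusted p = 0.230 and 0.570). With an estimated correlation both gave adjusted p = 0.678.

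Between animals of one tissue, values spread more in liver. The median SD over the 3 arrays was 0.259 in liver and 0.195 in cerebellum on the log2 scale, and the SD was larger in liver for 62.3% of 15077 features. Among 4811 features above the median level and within 2-fold between the tissues, the share was 60.1%. Replicate 3 decides this value. Without replicate 3 in both tissues the share was 49.4%, without replicate 1 it was 54.3% and without replicate 2 it was 70.3%.

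**Figure D3:**
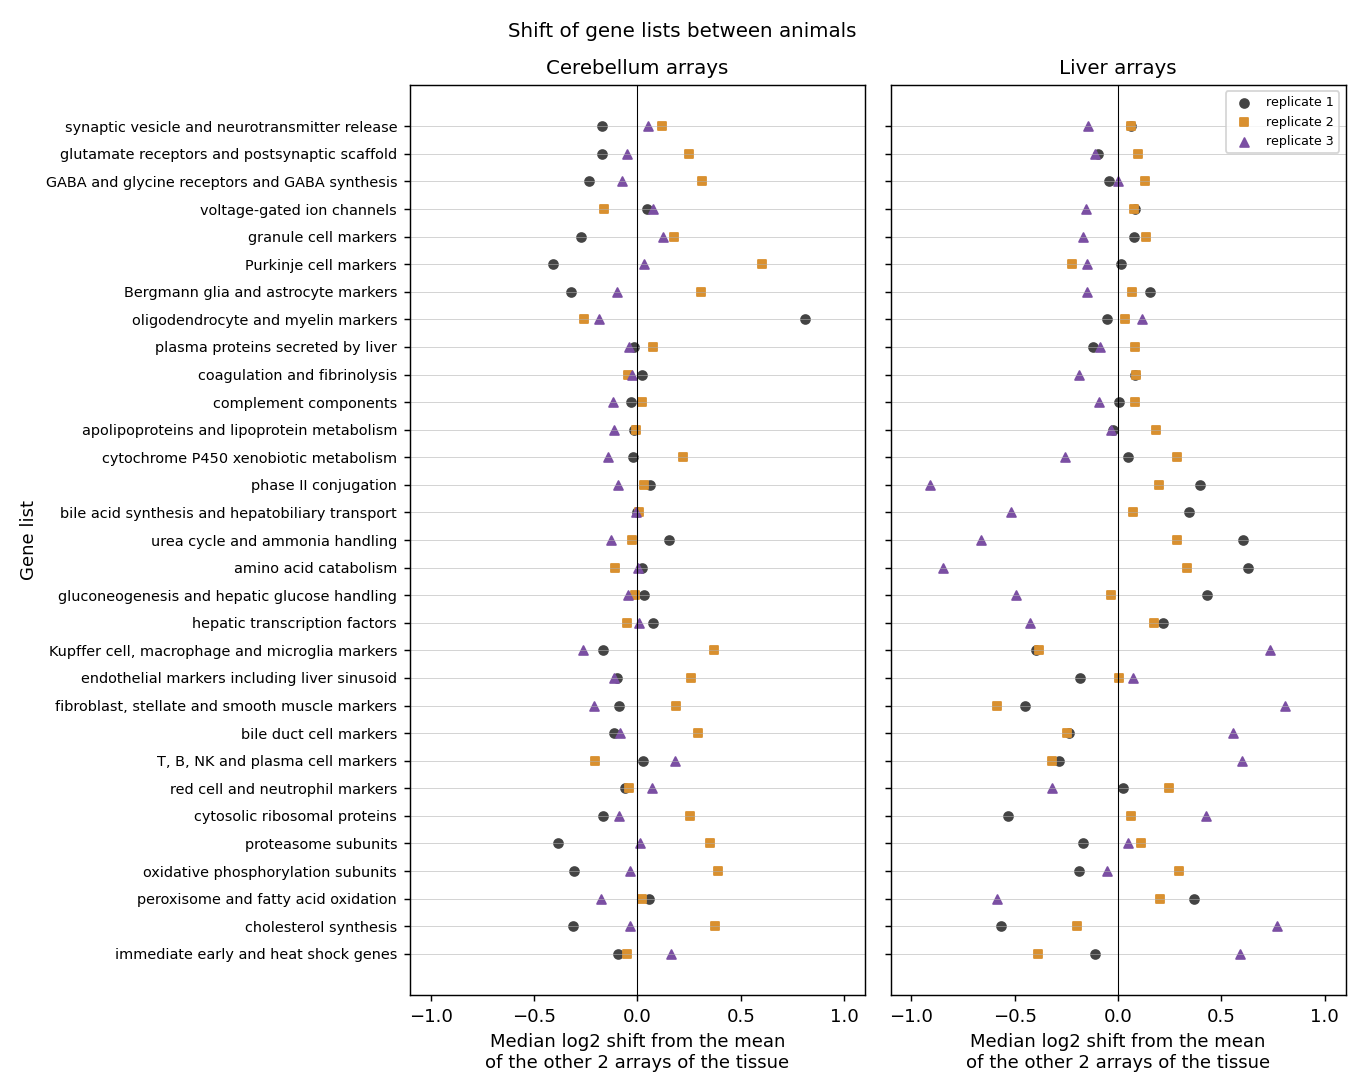
Median log2 shift of each gene list on each array, from the mean of the other 2 arrays of its tissue, with cerebellum on the left and liver on the right. In liver replicate 3 macrophage markers lie at 0.74, amino acid catabolism at -0.84, and red cell and neutrophil markers at -0.32. Oligodendrocyte markers lie at 0.81 in cerebellum replicate 1 and Purkinje markers at 0.60 in cerebellum replicate 2.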

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

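The alignment on general genes, the removal of features with a value below 0 and the fit without both cerebellum replicate 1 and liver replicate 3 were chosen after the data were seen. Renewed quantile normalization and centring on the median move nothing in a table whose arrays share one distribution, so they test nothing and are not counted here. Of 102 alternative values for counts of features, 98 stayed within 1.5 times the reported count, as did 442 of 465 for counts of list members. With an estimated correlation in camera, 23 of the 27 called list shifts no longer passed and 4 did. Correlation among the genes of a list does not account for all of this. The glutamate and apolipoprotein lists had estimates of -0.010 and -0.062, under the preset 0.01. Camera's adjusted p still rose for them, from 1.71e-07 and 5.74e-08 to 0.0332. Under the other alternatives, list shifts kept their side of the threshold and direction in 461 of 465 values. Named genes did so in 836 of 866. The shifts and genes that no longer passed kept their direction. With arrays aligned on ribosomal protein, proteasome and oxidative phosphorylation genes, 2305 features were higher in liver, 2 proteasome genes and 2 red cell and neutrophil genes were higher in liver, and 2 ribosomal protein genes were higher in cerebellum. The alignment itself moves every difference toward cerebellum. In the test against a 2-fold difference (treat), 2645 features passed, 1295 higher in cerebellum and 1350 higher in liver, which follows from its stricter null hypothesis. Without dim features, 6 lymphocyte genes and 2 red cell and neutrophil genes of those left on the lists were higher in liver, and the SD was larger in liver for 60.4% of features. At the pseudocount of the 1st percentile, 0 ribosomal protein genes and 1 oxidative phosphorylation gene were higher in cerebellum and 6 proteasome genes were higher in liver, and the cause was not tested. Without both cerebellum replicate 1 and liver replicate 3, the counts were 0, 1 and 4 for these lists, with fewer samples. Leaving out each array in turn gave 0 to 1 ribosomal protein genes and 0 to 2 oxidative phosphorylation genes higher in cerebellum, and 5 to 12 proteasome genes higher in liver. Leaving out each replicate number in turn gave a larger SD in liver for 49.4% to 70.3% of features. The value under a majority came without replicate 3.

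The labels give same-numbered samples of both tissues the same sex and age and do not name the animal. Deviations from the tissue mean correlated across features at 0.11, 0.16 and -0.14 for replicates 1, 2 and 3, and cerebellum replicate 3 correlated best with liver replicate 1, at 0.24. With 3 arrays per tissue these correlations cannot tell whether the animals are shared. The plan, fixed before the data were examined, took a shared animal per number as probable. It held the block as an alternative, and the main fit has none. With a replicate block, 3994 features were higher in cerebellum and 3538 in liver. The block changed 0 of the calls on feature counts, list counts and list shifts beyond the bounds above, and 60 of 62 named genes stayed on their side of the threshold. The exceptions were OPALIN (limma, adjusted p = 0.0557) and RPS6 (adjusted p = 0.0678). This pairing check was read together with the blocked counts. Dim genes are limited by the signal over background, since 297 features had a value below 0 on at least 1 array.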

Other observations

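Apart from the division of the 6 arrays into other groups, the tests in this part were chosen after the results were seen, and so were the gene families, the genes named, the arrays and the intensity window they use. In 48 families defined by gene symbol, 2 of which had no measured gene, 14 shifted against other genes (limma's camera, adjusted p under 0.05). With an estimated correlation none of the 14 passed, with adjusted p from 0.333 to 0.560, and their medians kept their direction when arrays were aligned on general genes. Among 23 calcium channel genes 17 were higher and 0 lower, with a median log2 difference of 1.12, and the P/Q-type channel CACNA1A was at 1416 ± 451 in cerebellum and 36.9 ± 6.80 in liver (intensity, mean ± SD, n = 3). Potassium channel genes had 28 higher and 4 lower of 75, protocadherins 12 and 3 of 20, and RAB genes 22 and 9 of 54. For comparison, 3327 of all 12584 named genes were higher and 3074 lower. Of 13 genes whose symbol starts with TUB, 8 were higher and 1 lower, led by TUBB4A at 1253 ± 221 against 11.7 ± 7.87. Of 55 genes whose symbol starts with MAP, 27 were higher and 7 lower, a prefix that also takes in kinases, and among them were the microtubule-associated proteins MAP1B and MAP2 with log2 differences of 4.88 and 4.33. Chromatin remodelling genes of the CHD and SMARC families had 9 higher and 0 lower of 17, with a median of 0.85. SMARCD3 differed by 2.88.

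Of 5 alcohol dehydrogenase genes 4 were higher in liver and 0 in cerebellum, and ADH1B was at 12.5 ± 4.49 in cerebellum and 2706 ± 309 in liver, a value that near-identical copies can share. Of 17 aldehyde dehydrogenase genes 11 were higher in liver and 0 in cerebellum. SERPIN genes had 12 higher in liver and 2 in cerebellum of 24, and cytochrome P450 genes 19 and 3 of 35. Of 22 chemokine genes of the CXCL and CCL families 11 were higher in liver and 1 in cerebellum, with a median of -1.29, and CXCL12 was at 63.7 ± 10.7 against 938 ± 149.

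In liver replicate 3, marker lists of macrophages, fibroblasts, lymphocytes and bile duct lay above the other 2 livers (0.74, 0.81, 0.60 and 0.55). Most lists of hepatocyte metabolism lay below, while endothelial markers lay at 0.07 and red cell and neutrophil markers at -0.32. These last medians hide opposite moves. Of 14 endothelial genes 7 lay above, with CDH5 at 0.94 and CLEC4M at -1.53. Of 11 red cell and neutrophil genes 3 lay above, with HBB at 1.32 and S100A9 at -0.61. COL1A1 was at 600 on this array against 78.5 and 74.5, and PCK1, an enzyme of gluconeogenesis, at 376 against 2646 and 2354. The 82 genes on these 6 lists shifted by a median of 0.48, at percentile 100 of random lists of the same intensity. Of these genes, 2 are also on cerebellum or liver lists. The array was picked because shifts of such lists stood out, so the percentile cannot decide on an intensity-dependent distortion. It shows only that random lists of the same intensity shifted less. A lower share of hepatocytes alone would raise the other cell types alike, but the medians of the 6 lists spread more than when genes of similar intensity were exchanged among lists (permutation p = 0.0118 over 100000 draws). However, fibroblast minus endothelial markers taken alone gave 0.73 with a bootstrap interval over genes of -0.59 to 1.67, a width judged undecided only once the interval was known. The permutation test takes each list to move as a unit, which the mixed red cell and neutrophil list did not, so it does not settle this point. Whether hepatocyte genes fell alike stays open, because the same test over the 11 liver lists, on 108 genes at intensities from 200 to 2000, gave permutation p = 0.0504, and both tests treat genes as independent, which makes p too small where genes of a list vary together. A lower share of hepatocytes may contribute, alone or together with other changes. A difference in the state or handling of this liver stays open too, with cholesterol synthesis genes at 0.77, immediate early and heat shock genes at 0.59 and peroxisome and fatty acid oxidation genes at -0.58 on this array.

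Cerebellum replicate 1 was higher in myelin genes than the other 2 cerebella, with MBP at 4297 against 966 and 1481. The oligodendrocyte list shifted by a median of 0.81, at percentile 100 of random lists of the same intensity. None of its 13 measured genes is on another list. The list and the array were picked because this shift stood out, so the percentile cannot decide on an intensity-dependent distortion. It shows only that random lists of the same intensity shifted less. A larger share of white matter in this sample is a candidate explanation that stays open, because the 84 neuronal genes shifted by a median of -0.20 but 45 ribosomal protein, proteasome and oxidative phosphorylation genes by -0.30, and the difference of 0.11 had a 95% bootstrap interval of -0.02 to 0.23. That interval resamples genes of this array, so it does not cover the spread between animals. Cerebellum replicate 2 differed from the other 2 in the opposite direction, with Purkinje markers at 0.60 and the proteasome list at 0.35, and it is part of the mean that replicate 1 is set against. Replicate 1 was also the only female and the youngest, and an effect of sex or age stays open as untested.

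The zinc finger genes that were called lay mostly higher in cerebellum, and the mitochondrial ribosomal protein genes that were called lay mostly higher in liver. Of 292 ZNF genes 154 were higher in cerebellum and 11 in liver, with a median of 0.64 (camera, adjusted p = 7.12e-08, but adjusted p = 0.333 with an estimated correlation), and of 54 MRPL and MRPS genes 2 and 29, with a median of -0.67 (adjusted p = 0.00159, but 0.560 with an estimated correlation); ZNF483 and MRPL40 differed by 5.40 and -2.44. With arrays aligned on general genes the counts were 181 and 3 for ZNF genes and 4 and 12 for MRPL and MRPS genes, with medians of 0.98 and -0.33, and without cerebellum replicate 1 and liver replicate 3 they were 131 and 8, and 0 and 22. One scaling offset between the tissues would move random lists as well. The zinc finger median lay at percentile 100 and the mitochondrial ribosomal median at 0.01 of random lists of the same intensity. The larger two-sided p from 10000 such lists, multiplied by the 46 families measured, was 0.0184. That p takes genes as independent, which makes it too small where genes of a family vary together. The families were also chosen after the results were seen. The percentiles therefore cannot decide on an offset or on an intensity-dependent distortion, and show only that random lists of the same intensity shifted less. Signal shared among zinc finger paralogs may add to the count and stays open, since their mean correlation within tissues was 0.048, again at percentile 100 of random lists. A difference between the tissues themselves is another open explanation.

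For the main comparison, the 6 arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The division by tissue, 1 of the 10, gave 7662 features past the threshold, 4997 of them at least 2-fold, and 347 listed genes, and the highest count in any other division was 0 for all 3 values. Every other division mixes the tissues, so their difference enters the spread within groups and such counts are low by construction.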
